A study of Mus musculus with 24 samples.

How the data were processed

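Small RNA of mouse cortex was measured in 24 libraries: APP/PS1 and WT mice of strain C57BL/6 at 1, 3, 6 and 9 months, with 3 mice per group. The series title names the cerebral cortex, and the tissue label of each library reads brain. Per the labels' protocols, brains were flash frozen after cervical dislocation, RNA was extracted with Trizol, and TruSeq small RNA libraries were read single-end on a HiSeq 2500. The labels give 2 female and 1 male mouse per age group without the sex of each library, so sex was not modelled.

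Per the submitters' processing notes, adapters were removed with cutadapt 1.14, keeping reads of 17 to 35 bases, reads with quality under 20 were removed with Trimmomatic 0.36, and reads matching rRNA, tRNA, snRNA, snoRNA or repeats were removed with BLAST 2.6.0. Known miRNAs came from miRBase 21.0 and predicted ones from miRDeep2 2.0.0.8. The tool that counted reads, the treatment of reads matching several names and the genome build are not given in the sources used here. The authors named edgeR with neither version nor model. The deposited values are raw counts per mature miRNA name, as the authors made them, in 1 table of 1927 names by 24 libraries, matched to the libraries by their descriptions. Every value was a whole number, 0 libraries were identical, 802 names had 0 counts everywhere, and 12 names were of predicted miRNAs. Predicted miRNAs are described here by the known miRNA whose counts they follow. mRNA data that the series title mentions were not analysed here.

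Library totals lay between 2230030 and 6829622 counts. Names were kept with edgeR's filter by expression (minimum count 10, minimum total 15), which left 433, of which 9 were predicted. The names left out held between 0.011% and 0.0159% of the counts of a library. Among the 433 were 15 sets of names with identical counts in all libraries, 32 names together, such as miR-199a-3p and miR-199b-3p, miR-486a-5p and miR-486b-5p, and these are not independent. Replicates varied beyond counting noise, with a chi-square per degree of freedom between 37 and 944 within groups, and the common biological coefficient of variation was 18.6%.

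Counts were scaled with TMM and fitted in edgeR 4.0.16 (R 4.3.3) by quasi-likelihood, with 1 mean per group over 8 groups, 16 residual and 4.64 prior degrees of freedom. The 11 comparisons were APP/PS1 against WT at each age, that difference averaged over ages, its variation over ages, 3 against 1, 6 against 3 and 9 against 6 months over both genotypes, and 9 against 1 month in each genotype. P-values were adjusted by Benjamini and Hochberg within each comparison at 0.05. They measure the spread between mice. Standard errors are the size of the log2 fold change divided by the square root of its F. CPM are given as mean and SD over libraries. The genotype difference at 1 age was also tested against its mean at the other 3 ages. Each 3 against 3 comparison was checked for libraries of both groups that do not overlap, which chance gives for 10% of miRNAs.

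miRNAs were named by a rule set before the data were examined: per comparison the 12 higher and the 12 lower with the smallest p among those passing, and not overlapping for 3 against 3; the 3 with the smallest p where fewer than 3 passed; up to 4 passing members per list; the panel often studied in Alzheimer disease in genotype comparisons; and the 5 most abundant. Named outside this rule, after their values were seen, were miR-486a-5p, miR-486b-5p, miR-486a-3p, miR-486b-3p, miR-223-3p, miR-150-3p, miR-150-5p, miR-146b-5p, miR-126a-3p and miR-143-3p at 9 months, miR-466i-5p and miR-466i-3p at 3 months, and let-7d-5p and miR-21a-5p, besides those of the closing section so described.

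The lists of miRNAs and their tests were also set before the data were examined. There were 18, of which 15 had 3 or more tested members and entered camera of limma 3.58.1 on voom values with a preset correlation of 0.01, with an estimated correlation as the alternative. The 150 p-values were adjusted together. Names with identical counts entered the lists singly, such as miR-486a-5p and miR-486b-5p in the erythrocyte list. In the Sfmbt2 list miR-297a-3p, miR-297b-3p and miR-297c-3p did so. List counts and camera p-values therefore rest on fewer distinct measurements than members. With the preset correlation 33 passed, and with an estimated correlation 0 did. The oligodendrocyte list (1 tested member), the list of the miR-200 family and miR-183 cluster (0) and the Hox cluster list (2) were not testable. Lists with at least 1 passing test were the erythrocyte, immune and microglial, striated muscle and liver, miR-17-92, Dlk1-Dio3, Sfmbt2, brain age, App and Bace1, and Alzheimer panel lists. The neuron-enriched (16 tested), activity-regulated (6), choroid plexus (4), endothelium and vascular smooth muscle (4), hypothalamus and pituitary (4) and let-7 (9) lists passed in 0 of 10 comparisons each. The choroid plexus list at 9 months had 1 of 4 members rising, miR-211-5p (adjusted p = 0.202).

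The pipeline was tested on simulated data with known changes in 67, 67 and 66 miRNAs at 1.5-fold, 2-fold and 4-fold and none in the other 233. At 9 months 41.8%, 68.7% and 95.5% of these changes were recovered, for the average over ages 85.1%, 98.5% and 100%, and for 6 against 3 months 71.6%, 94% and 100%. False calls made up 0.725%, 5.03% and 3.28% of the calls. A far larger share of miRNAs was changed in the simulation than passed in the data, where 16 of 433 passed at 9 months. A larger share eases passing after adjustment, and counts that stand out in 1 library were not simulated. Recovery and false calls may therefore be less favourable in the real data.

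Alternatives were DESeq2 1.42.0 (Wald test, likelihood ratio test for the variation over ages), its median-ratio size factors, no filter, known names only, a replicate block, only the groups compared (filter, scaling and spread taken from their libraries), and each library left out in turn. Merging identical names and leaving out the 6-month libraries were added after the data were seen. Each comparison was also repeated on other splits of its libraries. Precursors of GENCODE mouse release M21 (GRCm38), which may differ from the build the authors used, gave locations for 416 of the 433 names. They were aligned to annotated genes with blastn 2.17.0, counting other genes matched over at least 50% of the precursor at 80% identity or more, and a name with 20 or more such genes was called repeat-like. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.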

Results

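Small RNA was sequenced from the cerebral cortex of APP/PS1 mice, a transgenic model of Alzheimer disease, and of wild-type (WT) C57BL/6 mice at 1, 3, 6 and 9 months of age. Each of the 8 groups held 3 mice, which gave 24 libraries. The deposited counts per library summed to between 2230030 (WT 6-month replicate 1) and 6829622 (APP/PS1 1-month replicate 1). By deposited counts, miR-124-3p, the neuronal miRNA, ranked highest at 179840 ± 21526 CPM, counts scaled to library size (SD, n = 24). It was followed by miR-26a-5p at 91742 ± 12424 CPM, miR-99a-5p at 86204 ± 9965, miR-125b-5p at 62800 ± 12266 and miR-9-5p at 62412 ± 6484. This order is one of counts and not of molecules, since some names such as let-7d-5p (6 to 27 counts per library) and miR-21a-5p (1 to 7), chosen after their values were seen, were hardly counted at all. Of 1927 listed names, 424 known and 9 predicted miRNAs had enough counts to be tested. Values below are CPM as mean ± SD, and log2 fold changes with their standard error.

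The difference between APP/PS1 and WT mice was first taken at each age. At 1 month the 3p arms of the miR-29 family, whose members are described as targeting Bace1 transcripts, were higher in APP/PS1 cortex. miR-29b-3p stood at 1237 ± 31.7 CPM against 820 ± 81.3 in WT (n = 3 each), a log2 fold change of 0.59 (SE 0.10, adjusted p = 0.00175). miR-29c-3p stood at 1001 ± 55.0 against 698 ± 43.4 CPM, a log2 fold change of 0.52 (SE 0.09, adjusted p = 0.00175). miR-29a-3p, at 40.3 ± 3.72 against 27.0 ± 1.69 CPM, had a log2 fold change of 0.58 (SE 0.11, adjusted p = 0.00591). The precursors Mir29a (31062660 to 31062747) and Mir29b-1 (31063023 to 31063093) lie on chromosome 6 of GRCm38, and Mir29b-2 (195037040 to 195037120) and Mir29c (195037547 to 195037634) on chromosome 1, within the noncoding transcript A330023F24Rik and opposite Cd46.

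These 3 were the miRNAs that passed at 1 month in edgeR's quasi-likelihood test, with 28 at an unadjusted p under 0.05 where chance gives 21.7. In all 3, each APP/PS1 library lay above each WT library, which was so of 15.2% of all tested miRNAs in either direction, against 10% by chance. The call of miR-29a-3p was lost in 3 of 6 fits that left out a library (highest adjusted p = 0.0746, without APP/PS1 1-month replicate 2, log2 fold change 0.51), without a filter on low counts (adjusted p = 0.371) and in a fit of the 1-month libraries alone (adjusted p = 0.169). For none of the 3 did the difference at 1 month pass a test against the mean difference at the other ages (adjusted p = 0.102, 0.284 and 0.102 for miR-29a-3p, miR-29b-3p and miR-29c-3p).

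**Figure D1:**
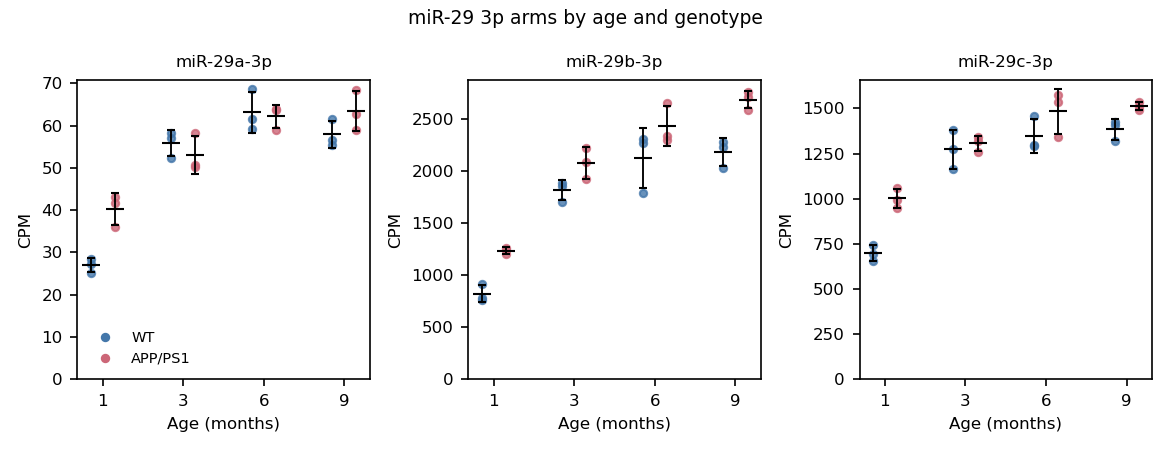
CPM of miR-29a-3p, miR-29b-3p and miR-29c-3p (vertical axes) by age in months (horizontal axes). Points are libraries, blue for WT and red for APP/PS1, with mean and SD (n = 3) in black. At 1 month the APP/PS1 mean of miR-29b-3p was 1237 CPM against 820 in WT.

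Among the lists of miRNAs fixed before the data were examined, 3 of the 18 tested members of the list reported to target App or Bace1 transcripts rose at 1 month, as did 3 of the 15 of the list reported to change with brain age. In both lists these were the miR-29 arms, and the counts adjusted over the list alone were also 3. The App and Bace1 list passed the camera test (adjusted p = 0.00185; adjusted p = 0.308 with an estimated correlation), and so did the brain age list (adjusted p = 0.0157; adjusted p = 0.129 with an estimated correlation). The miRNAs of the imprinted Dlk1-Dio3 locus lay lower in APP/PS1 as a set (median log2 fold change -0.10 over 90 miRNAs, adjusted p = 6.75e-06; adjusted p = 0.234 with an estimated correlation), though 0 of them passed alone, adjusted over the list alone or over all tested. The miR-17-92 and paralogous clusters, which serve cell proliferation, had a median of -0.23 over 8 miRNAs (adjusted p = 0.033; adjusted p = 0.402 with an estimated correlation), and 0 passed alone or adjusted over the list alone.

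At 3 months no miRNA passed in edgeR's quasi-likelihood test, and DESeq2 gave 0 as well, with 11 at an unadjusted p under 0.05 in edgeR. The smallest p belonged to miR-376a-3p of the Dlk1-Dio3 locus, at 36.3 ± 6.07 CPM in APP/PS1 and 18.3 ± 0.836 in WT (n = 3 each; log2 fold change 0.99, SE 0.25, adjusted p = 0.313). miR-18a-5p (log2 fold change -0.87) and miR-101c (-0.60) followed at an adjusted p of 0.996. The Dlk1-Dio3 list lay higher in APP/PS1 (median 0.08, adjusted p = 0.000121; adjusted p = 0.302 with an estimated correlation) and the list of the rodent-specific cluster in an intron of Sfmbt2 lay lower (median -0.12 over 24, of which miR-466i-5p and miR-466i-3p come from chromosome 13, opposite Cdk13, adjusted p = 0.042; adjusted p = 0.751 with an estimated correlation). In neither list did a member pass, adjusted over the list alone or over all tested.

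At 6 months 0 miRNAs passed in edgeR's quasi-likelihood test and 0 in DESeq2, with 37 at an unadjusted p under 0.05. miR-100-5p had the smallest p, at 20793 ± 1864 CPM in APP/PS1 and 16161 ± 1268 in WT (n = 3 each; log2 fold change 0.36, SE 0.09, adjusted p = 0.302). miR-125a-5p (log2 fold change 0.91) and a predicted miRNA whose counts follow it (1.12), both with an adjusted p of 0.384, owed their difference to APP/PS1 6-month replicate 2. That library held miR-125a-5p at 59047 CPM against 18126 and 23587 in the other APP/PS1 libraries, and without it the log2 fold changes were 0.22 and 0.16. Without APP/PS1 6-month replicate 1 the count of miRNAs passing was 7. No list passed at this age.

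At 9 months 16 miRNAs passed, 12 higher and 4 lower in APP/PS1. Of the 12, miR-690, a predicted miRNA that follows it, miR-1957a, miR-3470a and miR-6481 were also among the 8 names that rose by over 2 on the log2 scale from 3 to 6 months. Those 8 names summed to between 135.8 and 347.8 CPM in the APP/PS1 libraries at 9 months and 32.35 and 62.45 in WT. At 6 months the order of the genotypes was the reverse, with sums between 358.4 and 718.1 CPM in APP/PS1 and 916.9 and 1256 in WT. The precursors of miR-1957a and miR-3470a matched 52 and 4355 other annotated genes, and those of miR-690 and miR-6481 matched 0 and 1. Of the erythrocyte miRNAs, both arms of miR-144 and miR-451a were lower. miR-144-5p stood at 5.198 ± 1.11 CPM in APP/PS1 against 18.8 ± 2.11 in WT (n = 3 each) and fell by 1.84 on the log2 scale (SE 0.35, adjusted p = 0.00402). miR-144-3p fell by 1.56 (SE 0.37, adjusted p = 0.0166) and miR-451a, at 116 ± 65.2 against 294 ± 27.3 CPM, fell by 1.34 (SE 0.33, adjusted p = 0.0236). Mir144 (78073005 to 78073070) and Mir451a (78073170 to 78073241) adjoin each other on chromosome 11 of GRCm38, outside annotated protein-coding genes. Both arms of miR-142a, a miRNA of blood and immune cells, were higher. miR-142a-5p stood at 790 ± 146.6 against 510 ± 42.7 CPM (log2 fold change 0.63, SE 0.13, adjusted p = 0.00563) and miR-142a-3p at 17.0 ± 3.46 against 8.77 ± 1.91 CPM (log2 fold change 0.97, SE 0.22, adjusted p = 0.0158). The neuron-enriched miR-128-3p, at 26382 ± 2271 against 36143 ± 2945 CPM, fell by 0.45 (SE 0.12, adjusted p = 0.0401), and this call was lost in each of 6 fits that left out 1 of the 9-month libraries (highest adjusted p = 0.194, without APP/PS1 9-month replicate 3).

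Of the miRNAs higher at 9 months, miR-690 had 110 ± 59.5 CPM in APP/PS1 and 22.7 ± 8.08 in WT (log2 fold change 2.29, SE 0.42, adjusted p = 0.00402). Its precursor lies on chromosome 16 (28599935 to 28600043, GRCm38) within Fgf12. A predicted miRNA moved with it (log2 fold change 2.12), its counts lying between 0.583 and 0.876 of those of miR-690 in all 24 libraries. miR-1957a had a log2 fold change of 1.94 (SE 0.47) and miR-3470a of 1.54 (SE 0.36). miR-6481 had 50 counts over the APP/PS1 libraries and 0 in WT, which made it at least 22.3-fold higher against a floor of 3 counts over the WT group. miR-211-5p, abundant in choroid plexus and pigmented epithelium, stood at 12.6 ± 4.80 against 3.62 ± 1.38 CPM (log2 fold change 1.80, SE 0.38). Some calls rested on 1 library. miR-215-5p, a miRNA of intestine and kidney, had 334 CPM in APP/PS1 9-month replicate 1 and at most 6.35 in any other library. Without that library its log2 fold change of 6.10 became 1.76 (adjusted p = 0.107), and that of miR-3470a, whose call was lost in 4 of 6 such fits, became 1.03 (adjusted p = 0.255). miR-199a-5p and miR-199a-3p, with miR-199b-3p listed at identical counts, had log2 fold changes of 0.97 and 0.83, which became 0.45 (adjusted p = 0.371) and 0.35 (adjusted p = 0.394) without APP/PS1 9-month replicate 2.

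**Figure D2:**
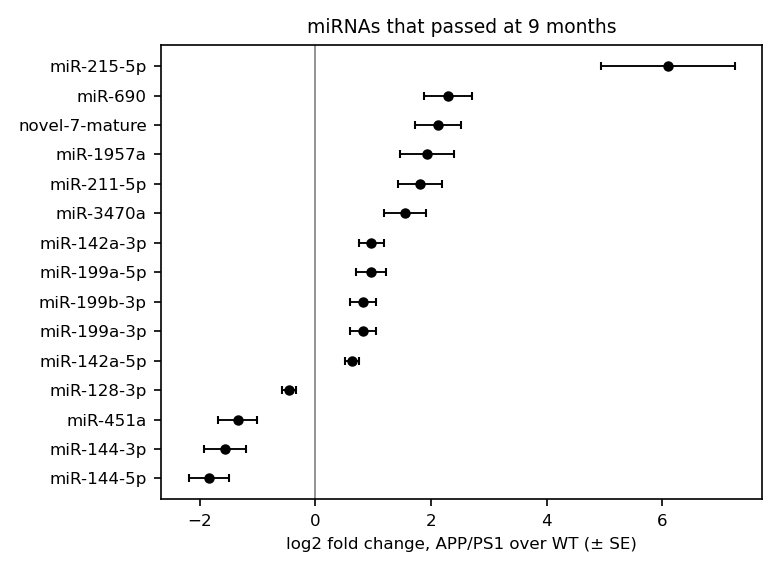
Log2 fold change of APP/PS1 over WT at 9 months (horizontal axis; bars are the SE) for the miRNAs that passed, except miR-6481, which had 0 counts in WT. miR-144-5p lies lowest at -1.84, and miR-215-5p, carried by 1 library, highest at 6.10.

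All 16 calls at 9 months had libraries of both groups that did not overlap, as did 18.2% of all tested miRNAs, against 10% by chance, and 47 miRNAs had an unadjusted p under 0.05. In a fit of the 9-month libraries alone, with filter, scaling and spread taken from them, 1 miRNA passed, miR-144-5p (adjusted p = 0.0104). Fits that left out 1 of the 6 libraries called between 6 (without WT 9-month replicate 2) and 17, and miR-144-5p, miR-142a-5p, miR-690 and the predicted miRNA that follows it passed in all 6. miR-451a passed in 1 of the 6 (highest adjusted p = 0.145, without APP/PS1 9-month replicate 1), miR-144-3p in 2 (0.0662, without the same library), miR-6481 in 2 (0.0902, without WT 9-month replicate 3), miR-1957a in 1 (0.118, without WT 9-month replicate 1), and miR-211-5p (0.0662, without APP/PS1 9-month replicate 1) and miR-142a-3p (0.114, without WT 9-month replicate 3) in 4.

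Of the 7 tested erythrocyte miRNAs, 3 fell at 9 months and 0 rose, with the same counts adjusted over the list alone (adjusted p = 6.76e-05; adjusted p = 0.136 with an estimated correlation). The other members, miR-486a-5p and its identically counted copy miR-486b-5p (log2 fold change -0.34, adjusted p = 0.546) and their 3p arms miR-486a-3p and miR-486b-3p (0.04, adjusted p = 0.976), did not pass. Of the 9 tested immune and microglial miRNAs, the 2 arms of miR-142a rose, and 4 rose adjusted over the list alone (adjusted p = 0.0338; adjusted p = 0.284 with an estimated correlation). Of its 9 members 6 had values above 0 and 3 below, the latter miR-150-3p (log2 fold change -1.07, adjusted p = 0.572), miR-150-5p (-0.19, adjusted p = 0.658) and miR-146b-5p (-0.15, adjusted p = 0.633). Those above 0 included miR-146a-5p (log2 fold change 0.54, adjusted p = 0.115), miR-155-5p (0.81, adjusted p = 0.323) and miR-223-3p (1.41, adjusted p = 0.0919), the last of which had 47.8 CPM in APP/PS1 9-month replicate 2 and at most 13.4 in any other library. The 4 endothelial and smooth muscle miRNAs tested did not pass, with miR-126a-3p at 0.02 and miR-143-3p at -0.01. The Sfmbt2 list had a median of -0.20 (adjusted p = 0.033; adjusted p = 0.724 with an estimated correlation), and 0 of 24 passed alone or adjusted over the list alone.

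**Figure D3:**
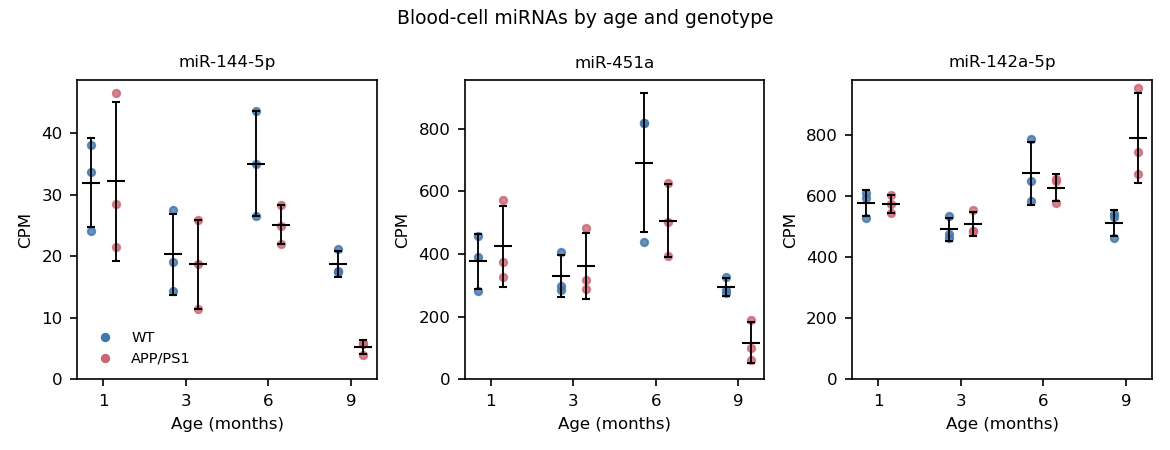
CPM of miR-144-5p, miR-451a and miR-142a-5p (vertical axes) by age in months (horizontal axes). Points are libraries, blue for WT and red for APP/PS1, with mean and SD (n = 3) in black. At 9 months miR-144-5p had a mean of 5.198 CPM in APP/PS1 and 18.8 in WT.

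Averaged over the 4 ages, with 12 mice of each genotype, 3 miRNAs passed. miR-29b-3p was higher in APP/PS1 by 0.32 on the log2 scale (SE 0.05, adjusted p = 0.00113) and miR-29c-3p by 0.21 (SE 0.04, adjusted p = 0.0176). Both averages include the difference at 1 month. That difference exceeded the mean of the other ages by 0.36 for miR-29b-3p and 0.42 for miR-29c-3p, though neither excess passed. At 3 months miR-29c-3p had a log2 fold change of 0.04, which turned direction in 3 of 6 fits that left out a library. miR-128-3p, at 30516 ± 4510 against 38219 ± 2816 CPM (n = 12 each), fell by 0.33 (SE 0.06, adjusted p = 0.00654). The calls of miR-29b-3p and miR-128-3p were kept in all 24 fits that left out 1 library, and that of miR-29c-3p in 22 (highest adjusted p = 0.0539, without WT 1-month replicate 2). Without a filter on low counts the call of miR-29c-3p was lost (log2 fold change 0.22, adjusted p = 0.165). There were 38 miRNAs at an unadjusted p under 0.05. By list, the erythrocyte miRNAs (median -0.11, all 7 below 0, adjusted p = 0.0013; adjusted p = 0.234 with an estimated correlation), of which 2 fell adjusted over the list alone, and the Sfmbt2 cluster (median -0.19, 23 of 24 below 0, adjusted p = 0.000242; adjusted p = 0.454 with an estimated correlation) lay lower. The list of single miRNAs often studied in Alzheimer disease lay higher (median 0.10, adjusted p = 0.0306; adjusted p = 0.402 with an estimated correlation), with 1 of 13 members rising, miR-29c-3p, and 1 adjusted over the list alone. Among its other members, miR-132-3p had an average log2 fold change of -0.04 (adjusted p = 0.935), miR-146a-5p of 0.16 (adjusted p = 0.626) and miR-125b-5p of 0.21 (adjusted p = 0.466).

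The list of miRNAs often studied in Alzheimer disease had 13 tested members: miR-9-5p, miR-29c-3p, miR-34a-5p, miR-107-3p, miR-124-3p, miR-125b-5p, miR-132-3p, miR-142a-5p, miR-146a-5p, miR-155-5p, miR-206-3p, miR-212-3p and miR-342-3p. At 1 month 1 of them rose, miR-29c-3p, and the 13 log2 fold changes lay between -0.13 and 0.52. At 3 months (-0.19 to 0.15) and at 6 months (-0.35 to 0.69) 0 passed, and at 9 months 1 rose, miR-142a-5p, within a range of -0.16 to 0.81, with 2 adjusted over the list alone. The highest value at 6 months was that of miR-342-3p (0.69, adjusted p = 0.842), which became -0.67 without APP/PS1 6-month replicate 1.

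Whether the genotype difference varied with age was tested over the 4 ages together. miR-690 and the predicted miRNA that follows it passed (adjusted p = 0.021 each), with 39 miRNAs at an unadjusted p under 0.05. Both calls were kept in 17 of 24 fits that left out 1 library (highest adjusted p = 0.134, without WT 9-month replicate 3). In the other 7 fits the count was 0: those without APP/PS1 6-month replicate 2, APP/PS1 9-month replicate 1, WT 6-month replicate 1 or 2, or any of the 3 WT 9-month libraries. The nearest miRNA that did not pass was miR-3470a (adjusted p = 0.102), followed in the fixed panel by miR-142a-5p (adjusted p = 0.119) and miR-29c-3p (adjusted p = 0.129). Without the 6-month libraries 1 miRNA passed, and neither miR-690 nor that predicted miRNA did.

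Change with age was then compared over both genotypes, with 6 mice at each age. From 1 to 3 months 78 miRNAs changed, 30 higher and 48 lower. All 3 miR-29 arms rose, miR-29b-3p from 1028 ± 235 to 1948 ± 182.8 CPM (n = 6 each; log2 fold change 0.95, SE 0.07, adjusted p = 6.17e-09), miR-29c-3p by 0.63 (SE 0.06) and miR-29a-3p by 0.72 (SE 0.08). miR-124-3p rose by 0.34 (SE 0.07) and the muscle miRNAs miR-133a-3p by 0.66 (SE 0.13) and miR-133b-3p by 0.62 (SE 0.16). Of the 90 tested miRNAs of the Dlk1-Dio3 locus, whose 50 precursors span positions 109563692 to 109747960 of chromosome 12 (GRCm38), 30 fell and 4 rose (34 and 5 adjusted over the list alone; adjusted p = 8.7e-09, and adjusted p = 0.118 with an estimated correlation). miR-412-5p fell by 1.57 (SE 0.13, from 225 ± 44.3 to 75.3 ± 3.06 CPM, adjusted p = 2.7e-08), miR-1197-3p by 2.04 (SE 0.21), miR-433-5p by 0.74 and miR-323-3p by 0.81, while miR-376b-5p (0.36) and miR-540-5p (0.39) rose.

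Several other lists changed between 1 and 3 months. In the miR-17-92 and paralogous clusters 4 of 8 fell, among them miR-18a-5p by 0.82 and miR-19a-3p by 0.63, and 5 adjusted over the list alone (adjusted p = 0.0338; adjusted p = 0.402 with an estimated correlation). In the Sfmbt2 cluster 3 of 24 fell, and 5 adjusted over the list alone (adjusted p = 0.0104; adjusted p = 0.638 with an estimated correlation). In the muscle list 3 of 6 rose, and 4 adjusted over the list alone (adjusted p = 0.0111; adjusted p = 0.299 with an estimated correlation). The App and Bace1 list had 6 of 18 rising (adjusted p = 0.00411; adjusted p = 0.367 with an estimated correlation) and the brain age list 3 of 15 (adjusted p = 0.00662; adjusted p = 0.118 with an estimated correlation), with the same counts adjusted over the list alone. Of the lists that did not pass, the erythrocyte list had 3 of 7 falling and all 7 below 0 (median -0.45, adjusted p = 0.0593), the Alzheimer panel 2 of 13 rising, the neuron-enriched list 3 of 16 rising, the let-7 family 1 of 9 (let-7b-5p, 0.24), the activity-regulated list 1 of 6 (miR-132-5p, 0.39) and the hypothalamic and pituitary list 1 of 4 falling (miR-7b-5p, -0.59), with the same counts adjusted over the list alone. miR-338-3p, an oligodendrocyte miRNA and the 1 tested member of its list, rose by 0.76 (SE 0.22, adjusted p = 0.0242) from 2.16 to 3.65 CPM. Calls lost in some of 12 fits that left out 1 library included those of miR-338-3p (highest adjusted p = 0.071) and miR-132-5p (0.0952), both without WT 3-month replicate 2, and of let-7b-5p (0.0746) and miR-7b-5p (0.0635), both without APP/PS1 1-month replicate 3. Of the 78 main calls, between 48 (without WT 3-month replicate 2) and 73 were kept in these fits. Without WT 3-month replicate 2, 12 miRNAs passed as higher, against 30 in the main fit. Fits that left out 1 library called between 49 (without WT 1-month replicate 2) and 95.

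From 3 to 6 months 52 miRNAs changed, 28 higher and 24 lower. A small group of miRNAs of low abundance rose over 4-fold: miR-690, from 19.7 ± 6.75 to 432 ± 197 CPM (n = 6 each; log2 fold change 4.35, SE 0.32, adjusted p = 1.5e-09), the predicted miRNA that follows it (4.06, SE 0.30), miR-3470a (4.10, SE 0.27), miR-3470b (3.79, SE 0.32), miR-1957a (3.11, SE 0.32) and miR-3471 (2.82, SE 0.45). miR-6481 went from 0.0307 CPM, near 0 counts, to 8.54 CPM, and miR-1195 rose by 1.69 (SE 0.26). Over all 24 libraries miR-6481 had 259 counts, 111 of them in 1 library, so the size of its rise is uncertain. The precursors of miR-3470a, miR-3470b, miR-1957a, miR-3471 and miR-1195 each matched 20 or more other annotated genes, 4355 in the case of miR-3470a. Reads of repeats might thus be counted under these names, though the submitters removed reads matching repeats. Matches of the mature reads were not tested. miR-1969, with 262 counts over all 24 libraries and at most 32 in any, fell from 2.55 to 0.129 CPM. miR-376c-3p fell by 1.13 (SE 0.19) and miR-342-5p by 1.38 (SE 0.33). miR-342-3p fell by 1.16 (SE 0.36, adjusted p = 0.0364), and its libraries at 6 months lay far apart, at 778 to 1035 CPM in 4, 2888 in WT 6-month replicate 2 and 5376 in APP/PS1 6-month replicate 1.

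The named erythrocyte miRNAs rose between these ages, miR-451a by 0.78 (SE 0.23, adjusted p = 0.0307) and miR-486a-5p by 0.46 (SE 0.13, adjusted p = 0.0233), as did the immune miRNAs miR-142a-5p by 0.38 (SE 0.09) and miR-146b-5p by 0.21 (SE 0.07). Of the 7 tested erythrocyte miRNAs 3 rose, and 6 adjusted over the list alone (adjusted p = 0.00336, and adjusted p = 0.299 with an estimated correlation). The 3 include miR-486a-5p and its identically counted copy miR-486b-5p. Of the Dlk1-Dio3 miRNAs 15 fell and 0 rose (18 and 0 adjusted over the list alone; adjusted p = 4.27e-06, and adjusted p = 0.226 with an estimated correlation), among them miR-412-5p by 0.89 (SE 0.14), miR-409-5p by 0.48 and miR-337-5p by 0.44. Of the lists that did not pass, the immune list had 2 of 9 rising and the brain age list 3 of 15 rising (5 adjusted over the list alone), miR-29b-3p among them by 0.23. The call of miR-451a was lost in 7 of 12 fits that left out 1 library (highest adjusted p = 0.0951, without WT 6-month replicate 1). Without that library the calls of miR-486a-5p (adjusted p = 0.103), miR-146b-5p (0.156) and miR-342-3p (0.086) were also lost, as was that of miR-29b-3p without APP/PS1 3-month replicate 1 (0.148), and in a fit of the 3-month and 6-month libraries alone 31 miRNAs passed.

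**Figure D4:**
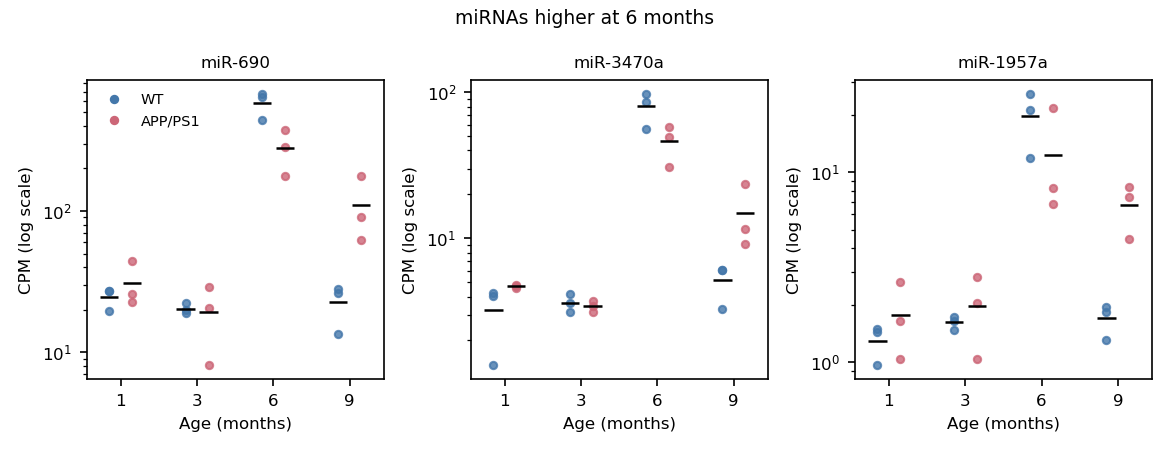
CPM (vertical axes, log scale) of miR-690, miR-3470a and miR-1957a by age in months (horizontal axes). Points are libraries, blue for WT and red for APP/PS1, dashes are means (n = 3), and no error bars are drawn. Over both genotypes miR-690 had a mean of 432 CPM at 6 months.

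From 6 to 9 months 31 miRNAs changed, 14 higher and 17 lower. miR-690 fell by 3.02 on the log2 scale (SE 0.29, from 432 ± 197 to 66.4 ± 61.1 CPM, n = 6 each, adjusted p = 2.18e-07), the predicted miRNA that follows it by 2.81, miR-3470a by 2.81, miR-3470b by 2.58, miR-1957a by 2.16 and miR-3471 by 2.61. Among the erythrocyte miRNAs, miR-451a fell by 1.68 (SE 0.24, from 600 ± 187.6 to 205 ± 107.5 CPM, adjusted p = 3.81e-05), miR-144-5p by 1.58, miR-144-3p by 1.22 and miR-486a-5p by 0.69. miR-100-5p rose by 0.70 (SE 0.06, from 18477 ± 2910 to 29858 ± 1838 CPM, adjusted p = 1.18e-07), miR-376c-3p by 0.92, miR-342-5p by 1.35 and miR-342-3p by 1.29 (SE 0.36, adjusted p = 0.0277). miR-1969 rose from 0.129 to 2.01 CPM.

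Of the 7 tested erythrocyte miRNAs 5 fell and 0 rose, with the same counts adjusted over the list alone (adjusted p = 2.53e-06, and adjusted p = 0.118 with an estimated correlation). The 5 include miR-486a-5p and its identically counted copy miR-486b-5p. The Dlk1-Dio3 list turned upward, with 6 rising, among them miR-433-5p by 0.43, and 2 falling, among them miR-299a-3p by 0.54 (9 and 2 adjusted over the list alone; adjusted p = 0.00185, and adjusted p = 0.405 with an estimated correlation). In a fit of the 6-month and 9-month libraries alone 16 miRNAs passed, and 53 passed without a filter on low counts. The call of miR-342-3p was lost in 5 of 12 fits that left out 1 library (highest adjusted p = 0.0725, without WT 6-month replicate 3).

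Age was last compared between 1 and 9 months within each genotype. In WT cortex 76 miRNAs changed, 31 higher and 45 lower. miR-29b-3p rose from 820 ± 81.3 to 2182 ± 134.4 CPM (n = 3 each; log2 fold change 1.41, SE 0.10, adjusted p = 2.92e-09), miR-29c-3p by 0.99 and miR-29a-3p by 1.10. miR-338-3p rose by 1.65 (SE 0.30), miR-101b-3p by 0.77, miR-100-5p by 0.53, miR-30a-5p by 0.68 and miR-133a-3p by 0.75. miR-412-5p fell by 2.59 (SE 0.20, from 252 ± 49.5 to 41.9 ± 2.66 CPM), miR-1197-3p by 2.26, miR-323-3p by 1.27, miR-494-3p by 0.98 and miR-409-5p by 0.81. The Dlk1-Dio3 list had 29 falling and 2 rising (30 and 3 adjusted over the list alone; adjusted p = 8.7e-09, and adjusted p = 0.118 with an estimated correlation). Of the miR-17-92 and paralogous clusters 6 of 8 fell, miR-18a-5p by 1.5, miR-19a-3p by 1.18 and miR-17-5p by 0.60 among them, and 6 adjusted over the list alone (adjusted p = 0.00176; adjusted p = 0.226 with an estimated correlation).

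In WT mice the Sfmbt2 cluster had 4 of 24 falling, and 7 adjusted over the list alone (adjusted p = 0.0013; adjusted p = 0.544 with an estimated correlation). The brain age list had 4 of 15 rising, with the same count adjusted over the list alone (adjusted p = 0.00441; adjusted p = 0.118 with an estimated correlation). The App and Bace1 list had 5 rising and 2 falling (7 and 2 adjusted over the list alone; adjusted p = 0.00662, and adjusted p = 0.402 with an estimated correlation). The call of miR-124-3p, which rose by 0.30 (adjusted p = 0.0364), was lost in each of 6 fits that left out 1 library (highest adjusted p = 0.202, without WT 9-month replicate 2). The muscle list (2 of 6 rising, 3 adjusted over the list alone) and the let-7 family (1 of 9, 2 adjusted over the list alone) did not pass.

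In APP/PS1 cortex 63 miRNAs changed between 1 and 9 months, 31 higher and 32 lower, and fits that left out 1 library called between 27 (without APP/PS1 1-month replicate 2) and 56, with 31 without APP/PS1 9-month replicate 1, 36 without 9-month replicate 2 and 39 without 1-month replicate 3. miR-29b-3p rose from 1237 ± 31.7 to 2690 ± 86.1 CPM (n = 3 each; log2 fold change 1.12, SE 0.10, adjusted p = 1.25e-07), miR-29c-3p by 0.60 and miR-29a-3p by 0.65. miR-338-3p rose by 1.62, miR-203-3p by 0.79, miR-152-3p by 0.56 and miR-211-5p by 1.72. miR-690 rose by 1.82, a call lost without APP/PS1 9-month replicate 1 (log2 fold change 1.29, adjusted p = 0.0572). Among the erythrocyte miRNAs, miR-144-5p fell by 2.63 (SE 0.34, from 32.2 ± 12.9 to 5.198 ± 1.11 CPM, adjusted p = 1.97e-05), miR-144-3p by 2.18 and miR-451a by 1.87. Of the 7 tested, 5 fell, and 5 adjusted over the list alone (adjusted p = 3.68e-05; adjusted p = 0.129 with an estimated correlation). miR-412-5p fell by 2.10 and miR-409-5p by 0.83, and the Dlk1-Dio3 list had 12 falling and 0 rising (14 and 0 adjusted over the list alone; adjusted p = 8.01e-07, and adjusted p = 0.174 with an estimated correlation).

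In APP/PS1 mice 9 of the 24 Sfmbt2 miRNAs fell, miR-467c-5p by 1.91 and miR-466d-3p by 1.26 among them, and 11 adjusted over the list alone (adjusted p = 8.93e-06; adjusted p = 0.367 with an estimated correlation). The brain age list had 3 rising and 1 falling, with the same counts adjusted over the list alone (adjusted p = 0.0102; adjusted p = 0.118 with an estimated correlation), the App and Bace1 list 4 of 18 rising (4 adjusted over the list alone; adjusted p = 0.0183, and adjusted p = 0.454 with an estimated correlation), and the muscle list 1 of 6 rising, miR-133b-3p by 1.01 (2 adjusted over the list alone; adjusted p = 0.0381, and adjusted p = 0.402 with an estimated correlation). The immune list, with 4 rising and 1 falling (5 and 1 adjusted over the list alone), did not pass (adjusted p = 0.0662). miR-223-3p rose by 1.55 and miR-215-5p by 6.50, calls carried by APP/PS1 9-month replicate 2 and replicate 1, and without replicate 2 the log2 fold change of miR-223-3p was 0.40 (adjusted p = 0.524).

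The changes with age in the 2 genotypes were set against each other. Of the 31 miRNAs higher at 9 than at 1 month in WT and the 31 in APP/PS1, 13 were shared, where 2.22 would be shared by chance (Fisher's exact p = 8.03e-09). Of the 45 lower in WT and 32 lower in APP/PS1, 19 were shared, where 3.33 would be by chance (Fisher's exact p = 5.52e-13), and 0 changed in opposite directions. Fisher's test takes the names as independent, which identically counted names and those of the Dlk1-Dio3 locus are not. Both comparisons also share the estimate of spread of each miRNA, so the chance counts and p-values overstate the evidence. The APP/PS1 counts in this overlap are those of all 6 libraries, and the overlap was not repeated with a library left out. The miR-29 arms and miR-338-3p were among those higher in both, and miR-412-5p, miR-409-5p and miR-1197-3p among those lower in both. Across all tested miRNAs the log2 fold changes in the 2 genotypes had a correlation of 0.436. A test of the difference in the change with age between genotypes called 0 miRNAs in edgeR, with 48 at an unadjusted p under 0.05.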

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

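The miRNAs below stood out because their difference between APP/PS1 and WT varied between ages by a test of that difference itself. The tests of repeats, of the 2 explanations for miR-29 and of other splits were set before those results were seen, and the tests of a lasting change, of a 6-month batch and of the 9-month blood and immune miRNAs were chosen after.

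Over the 4 ages together the genotype difference of miR-690 and of the predicted miRNA that follows it varied (adjusted p = 0.021 for each). Summed with the other names that rose by over 2 on the log2 scale from 3 to 6 months, they lay lower in APP/PS1 than in WT at 6 months and higher at 9 months. WT had the lowest library total at 6 months and the highest at 9 months, and a link of these sums to library totals was not tested. The difference at 9 months exceeded the mean difference at the other ages by 2.56 on the log2 scale for miR-690, 2.34 for that predicted miRNA, 1.64 for miR-3470a, 1.79 for miR-211-5p, 0.651 for miR-142a-5p and 1.17 for miR-142a-3p. Of 6 fits that left out 1 library, the call at 9 months was lost in 4 for miR-3470a (log2 fold change 1.03, adjusted p = 0.255 without APP/PS1 9-month replicate 1) and in 2 each for miR-211-5p and miR-142a-3p. For miR-144-5p the difference between ages was -1.66. For miR-215-5p it was 6.03, carried by APP/PS1 9-month replicate 1, and for miR-199a-5p 1.135, miR-199a-3p 1.1 and miR-199b-3p 1.1, carried by APP/PS1 9-month replicate 2. In all, 11 of the 16 miRNAs that passed at 9 months differed in this test. The 16 were chosen by their difference at 9 months, which also enters this test, so a high share is partly built in. In the test over the 4 ages together only miR-690 and that predicted miRNA passed. The others of the 11 had adjusted p between 0.102 (miR-3470a) and 0.188 (miR-211-5p) there.

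The first pattern is the 28 miRNAs higher at 6 than at 3 months. Reads of repeats counted under miRNA names could account for part of it. Of the 26 with a precursor 6 were repeat-like, against 1 of 390 others (Fisher's exact p = 2.22e-07). Their share of 23.1% lay under the share set beforehand, so this test leaves it open for the 28 together. Among the 8 names that rose by over 2 on the log2 scale, 5 were repeat-like. The repeat-like names called rose by a median of 2.97, against 0.563 for the other names called. A lasting change with age is also left open for the 28: in WT their median difference was 0.727 at 6 months and 0.253 at 9 months, a ratio of 0.348. In WT the summed level of the 8 names did not stay up. It lay between 41.86 and 47.94 CPM at 3 months, 916.9 and 1256 at 6 months and 32.35 and 62.45 at 9 months. In APP/PS1 it lay between 135.8 and 347.8 CPM at 9 months. In the summed level of the 28, 6 libraries of other ages, all at 9 months, lay above every 1-month and 3-month library. The summed level was thus raised at 9 months as well as at 6 months. A separate change at 9 months would give the same result, so the test cannot decide whether a batch of handling shared by the 6-month mice caused the rise at 6 months. The 28 were also chosen in these same libraries for lying lower at 3 than at 6 months. That sum is dominated by abundant names, so it shows little of the 8 names that rose by over 2 on the log2 scale. For those 8, all 3 APP/PS1 and 0 of 3 WT libraries at 9 months lay above every 1-month and 3-month library. A batch of the 6-month mice, with or without the APP/PS1 9-month mice, therefore remains possible and could not be tested.

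The second pattern is the lower miR-144 and miR-451a, 3 of the 7 tested erythrocyte miRNAs, and higher miR-142a at 9 months in APP/PS1. Less residual blood in the tissue may account for miR-144 and miR-451a, but the difference of miR-486a-5p exceeded that of miR-451a by 0.998 on the log2 scale (SE 0.382). That SE takes these miRNAs as independent, though both were measured in the same libraries. As other sources of miR-486a-5p were also not measured, the test leaves less residual blood open. White cells of residual blood are not settled as a source of miR-142a. miR-451a of the red cells differed by -1.34, where more residual blood would raise it. It does not measure white cells relative to red cells, so the test cannot decide this. More immune cells in the tissue might raise miR-142a, yet the immune list without it, with a median of 0.349, did not pass limma's camera test at 0.05 (0.39, unadjusted), which does not settle the matter.

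The third pattern is the higher miR-29 arms in APP/PS1 at 1 month. As miR-29 rose from 1 to 3 months, APP/PS1 mice further along that change could show it, and without miR-29 their libraries lay 0.132 of the WT step further along (exact p = 0.4, smallest possible 0.1), which leaves this open. Reads of 1 member counted under the name of another may explain miR-29a-3p, whose ratio to miR-29c-3p was the same in all libraries within counting noise (chi-square per degree of freedom 1.39, p = 0.0994). The ratio of miR-29b-3p to miR-29c-3p ranged from 1.13 to 1.8 over all libraries (chi-square per degree of freedom 68.4). The counts of miR-29b-3p were thus not a fixed multiple of those of miR-29c-3p. That range spans all ages, so the test cannot decide whether shared reads explain the difference of miR-29b-3p at 1 month.

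Other splits of the same libraries were compared with the real groups. At 1 month 1 of 10 splits, the real one, called 3 miRNAs and the highest other called 0; at 3 months all 10 called at least the real 0, with 0 the highest other; at 6 months all 10 did, with 2 the highest other; at 9 months 1 of 10 called 16 and the highest other 0. From 1 to 9 months 1 of 10 splits called 76 in WT and 1 of 10 called 63 in APP/PS1, with 0 the highest other in each. With 10 splits a share under 0.05 cannot be reached. Of 100 splits, 3 called as many as the real 3 for the average over ages (highest other 8), 3 as many as the real 2 for its variation over ages (7), 1 as many as the 78 from 1 to 3 months (66), 2 as many as the 52 from 3 to 6 months (52) and 1 as many as the 31 from 6 to 9 months (29).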

How the results depend on the processing

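Of the alternatives below, the merging of identical names and the fits without the 6-month libraries were chosen after seeing the data. Counts of calls kept within 1.5 times their main value are not repeated here. Without a filter on low counts, 8 miRNAs passed at 1 month, 2 at 3 months, 11 at 6 months, 13 averaged over ages, 27 for the variation over ages and 53 from 6 to 9 months, and 51 list tests passed. DESeq2 called 6 at 1 month, 6 averaged over ages and 13 for the variation over ages. With known miRNAs only, 1 passed for the variation over ages, as the predicted miRNA that follows miR-690 was then not tested. With only the groups compared, 1 passed at 9 months, 31 from 3 to 6 months and 16 from 6 to 9 months. Without the 6-month libraries 6 passed at 1 month, 1 at 3 months and 1 for the variation over ages, and 12 of the 16 main calls at 9 months also passed there. With an estimated correlation 0 list tests passed. Apart from the known names, the cause was not tested. Of the at most 197 passing results named by the rule, a miRNA counting once per comparison, 3 lost their call in DESeq2, 4 of 197 with its size factors, 33 of 197 without a filter, 43 of 190 with only the groups compared, 3 of 193 with known miRNAs only, 6 of 197 with identical names merged and 5 without the 6-month libraries, and 0 turned direction. Where each library was left out in turn, the counts ranged from 2 to 4 at 1 month, 0 to 0 at 3 months, 0 to 7 at 6 months, 6 to 17 at 9 months, 2 to 8 averaged over ages, 0 to 9 for the variation over ages, 49 to 95 from 1 to 3 months, 40 to 63 from 3 to 6 months, 25 to 49 from 6 to 9 months, 52 to 65 from 1 to 9 months in WT and 27 to 56 in APP/PS1. Names with too few counts for the filter were not tested, and how recovery depends on depth was not simulated.

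The replicate numbers do not pair mice by the labels. Of 12 pairs of equal number, with correlations from -0.413 to 0.22, 2 exceeded 0.1, and 4 of 24 libraries were closest to their own number. With the replicate block the counts were 3, 0, 0 and 15 at 1, 3, 6 and 9 months, 4 averaged over ages, 2 for the variation over ages, 71, 53 and 32 for the steps in age, and 75 in WT and 53 in APP/PS1, and 6 of 197 passing named results lost their call.

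The direction of 31 genotype results turned under some alternative, 30 in the panel and that of miR-26a-5p, and none of them had passed. In log2 units, without a filter on low counts miR-142a-5p at 1 month was 0.007008, miR-125b-5p at 3 months 0.002061 and miR-34a-5p averaged over ages 0.002689. With only the groups compared miR-34a-5p at 3 months was -0.002922. Without the 6-month libraries the averages of miR-212-3p and miR-342-3p were 0.0008151 and -0.08958, and with identical names merged that of miR-26a-5p was -0.004886. Of the 31, all except miR-142a-5p at 1 month and miR-125b-5p at 3 months turned in at least 1 fit that left out a library, and the cause was not tested. For the genotype difference at 1 month these ranges were miR-132-3p -0.1129 to 0.1333, miR-142a-5p -0.0728 to -0.01777, miR-206-3p -0.2759 to 0.5244, miR-34a-5p -0.5256 to 0.1071 and miR-9-5p -0.1306 to 0.05735. For the genotype difference at 3 months these ranges were miR-124-3p -0.01936 to 0.1012, miR-125b-5p -0.08159 to -0.0121, miR-132-3p -0.1618 to 0.04796, miR-142a-5p -0.05077 to 0.06667, miR-146a-5p -0.3608 to 0.006882, miR-206-3p -0.1929 to 0.814, miR-212-3p -0.032 to 0.01418, miR-29c-3p -0.05758 to 0.04858, miR-34a-5p -0.2443 to 0.3469 and miR-9-5p -0.06518 to 0.09759. For the genotype difference at 6 months these ranges were miR-132-3p -0.3335 to 0.1513, miR-142a-5p -0.1611 to 0.04139, miR-155-5p -0.3194 to 0.4804, miR-206-3p -1.274 to 0.07069, miR-212-3p -0.2232 to 0.09549, miR-342-3p -0.6651 to 1.594 and miR-9-5p -0.2486 to 0.007945. For the genotype difference at 9 months these ranges were miR-206-3p -0.1247 to 1.027, miR-212-3p -0.05941 to 0.03407 and miR-34a-5p -0.4879 to 0.07362. For the genotype difference averaged over ages these ranges were miR-132-3p -0.1151 to 0.005628, miR-206-3p -0.1675 to 0.2344, miR-212-3p -0.06831 to 0.008117, miR-342-3p -0.2528 to 0.3095, miR-34a-5p -0.1051 to 0.06925 and miR-26a-5p -0.02164 to 0.04099.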

Other observations

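The miRNAs and libraries named here were chosen after their values were seen. In APP/PS1 9-month replicate 1, the library that carried miR-215-5p, miR-192-5p, which shares its seed, had 1663 CPM and at most 1000.1 in any other library. miR-194-5p, which is transcribed with miR-192 and with miR-215, had 497 CPM in that library and at most 302 elsewhere. Along the first principal component, which held 33.5% of the variance, the 6-month libraries lay between 5.46 and 11.1, the APP/PS1 9-month libraries between 0.71 and 4.05, and all others below 0. miR-3470b also differed at 9 months from the other ages, though its difference at 9 months did not pass (log2 fold change 1.56, adjusted p = 0.0518).

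Some miRNAs known to be abundant in brain had few counts in every library. let-7d-5p had between 6 and 27 counts, let-7i-5p between 19 and 76, miR-21a-5p between 1 and 7 and miR-219a-5p between 0 and 2, while let-7a-5p had between 13246 and 35381 and let-7g-5p between 62509 and 185135. Differences were therefore tested between libraries within a name, and no low count was read as an absence. A predicted miRNA had between 0.541 and 0.843 of the counts of miR-125a-5p in every library.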
